A study of Mus musculus with 4 samples.

How the data were processed

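RNA was measured in regulatory T cells (Treg, the CD4 T cells that carry the transcription factor Foxp3 and restrain immune responses) of mice given an agonistic antibody against death receptor 3 (DR3, the product of Tnfrsf25) or a control antibody. Per the labels' protocols, the CD4 cells positive for a Foxp3 green fluorescent reporter were sorted 4 days after the antibody was injected into the peritoneum, and total RNA was labelled with biotin for Affymetrix whole-transcript arrays. There were 2 arrays per group. The labels do not say whether replicates came from separate mice, so the p-values measure only the spread between these arrays, which may be technical.

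The deposited values are intensities on a linear scale, 1 per probe set, made by robust multi-array average (RMA), per the submitters' processing notes. RMA corrects background, normalizes probe intensities between arrays to a shared distribution and summarises the probes of a probe set. The software, its version and the genome build are not given in the sources used here. The linear scale was read from the values, since all lay above 0 with array medians of 40.2 and 40.4 (anti-DR3) and 41.6 and 42.0 (control antibody), so log2 was taken before any test. Normalization to a shared distribution can hide a change that runs through all genes in one direction. For arrays, precision is limited by their number.

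Of 41345 probe sets, 23521 had 1 gene symbol in the platform annotation, 1814 had several and 16010 had none listed. Entrez identifiers matched 23328 of the probe sets with 1 symbol to a RefSeq gene table of GRCm38.p6, which updated 0 symbols. That table was used only for names, RNA classes and neighbouring genes. The unit of analysis was the gene, represented by the probe set with the highest mean. Genes above the median of all probe sets of an array on at least 2 of the 4 arrays were tested, which left 12114 genes and set aside 10066 as dim. For 1082 genes more than 1 probe set was present, and disagreement is stated where such a gene is named.

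The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Differences are anti-DR3 minus control antibody on the log2 scale, with their standard error (SE). The residual degrees of freedom were 2, and the prior added 3.94. An exact permutation test with 2 arrays against 2 cannot go below p = 0.333. Gene lists were tested with camera of limma at a preset correlation of 0.01 between genes, adjusted over the lists with at least 5 measured members. Camera with an estimated correlation, camera on ranks and fry were alternatives. Of 31 lists, 29 were tested: neutrophil and mast cell markers had 0 measured members and erythroid and platelet markers 2. For 70 listed genes no probe set with a single symbol was present, and they are not analysed here.

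The design, the lists, the rule for naming genes and the alternatives were fixed before the data were examined, except where the text says otherwise. The rule named Tnfrsf25, Tnfsf15 and Foxp3, then the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap, and up to 4 members of each list by the size of the moderated statistic. Predicted genes, clone names, small RNA families, olfactory and vomeronasal receptors, and antigen receptor segments were left out of that ranking. Segments were counted by symbol alone, and this rule also took Tradd, a signalling adaptor, and Ighmbp2, a helicase gene, which are not segments. The alternatives covered the replicate number as a block, each array left out, the filter on dim genes, normalization, the variance model, array weights, the choice of probe set, the threshold and the test.

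Probe sets with several symbols or none were outside the genes tested. Fitted with limma together with all other bright probe sets they gave 0 calls among 996 with several symbols, of which 212 lay under an unadjusted p of 0.05, and 0 among 7627 with no listed symbol, of which 1413 did. After that result had been seen, each kind was also fitted alone, which gave 17 higher and 4 lower among those with several symbols and 0 among those with none. The joint fit is the one reported, and no gene is named from the later one.

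The code was tested on 20 simulated sets of 12114 genes for this comparison, made from the measured means and the fitted spread, with 200 genes changed. It recovered 18.7% of genes changed by 0.5 on the log2 scale, 92.2% at 1 and 97.6% at 1.5, and 5.46% of its calls were false. Simulated arrays differed by independent noise only, so these shares do not cover differences that arrays share across genes. Their spread was drawn from the fitted prior, and fewer genes were changed than the 722 called in the data. The shares therefore show how the code works under its own assumptions, not its recovery or false share in these data. Figures were drawn with matplotlib 3.10.9.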

Results

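The data were 4 arrays of sorted mouse Treg, 2 from mice given the agonistic anti-DR3 antibody and 2 from mice given a control antibody, all taken 4 days after injection. DR3 is a receptor of the tumour necrosis factor (TNF) receptor superfamily that costimulates T cells. Arrays of the same group correlated at r = 0.992 (anti-DR3) and 0.989 (control antibody) over the 12114 genes tested, and arrays of different groups at 0.975 to 0.980. The comparison asked which genes of Treg differed after DR3 had been stimulated in the animal.

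After anti-DR3, 25 of 36 mitosis genes, 7 of 30 DNA replication genes and 25 of 32 effector Treg genes rose in limma, and 10 of 22 genes of resting Treg and naive T cells fell. Camera called these lists at its preset correlation but not with an estimated one (adjusted p = 0.215 with an estimated correlation for the lists that rose and 0.409 for the list that fell). Ccna2, a cyclin of S phase and mitosis, rose by 1.84 ± 0.096 (SE, n = 2 arrays per group) on the log2 scale, or 3.58-fold, and Mki67, the gene of the proliferation marker Ki-67, rose 3.44-fold (1.78 ± 0.099, adjusted p = 0.00606 for both, limma). Klrg1, a surface receptor of differentiated T cells, rose 2.78-fold (1.47 ± 0.14, adjusted p = 0.0102, limma). Pde3b, a phosphodiesterase, fell by 0.99 ± 0.090 on the log2 scale (adjusted p = 0.0102, limma). Foxp3 differed by 0.06 ± 0.081 (adjusted p = 0.671, limma), and Tnfrsf25 itself by 0.17 ± 0.093 (adjusted p = 0.305, limma). Tnfsf15, the ligand of DR3, was too dim to be tested, with log2 intensities of 5.25 and 5.66 after anti-DR3 and 5.16 and 5.24 after control antibody.

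In limma 722 genes passed an adjusted p of 0.05, 544 higher and 178 lower after anti-DR3, and 69 of the higher and 3 of the lower differed at least 2-fold. Once each array was centred on the median of the genes tested, the split was 348 higher and 243 lower. The groups did not overlap for 56.1% of genes tested, where chance gives 33.3% on average over the 3 ways to split the arrays. Genes on an array can vary together, so 1 split can exceed that share by chance. The count changed with each array left out, which also leaves 1 residual degree of freedom in place of 2. Limma called 33 genes without anti-DR3 replicate 1, 0 without anti-DR3 replicate 2 (1967 under an unadjusted p of 0.05), 96 without control antibody replicate 1 and 312 without control antibody replicate 2. The groups of all 722 did not overlap, so leaving out 1 array could not turn their direction. The count was also 14 with no filter on dim genes, 1281 with a stricter one, 1444 with a trended robust prior, and 0 both for every probe set tested on its own (4121 under an unadjusted p of 0.05) and for an ordinary linear model (2087).

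The 12 largest rises also held Kif11, Kif15 and Cenpe, motor proteins of the spindle, at 3.14-, 3.11- and 3.02-fold, and Nuf2 of the kinetochore at 2.95-fold. The others were Lilrb4a, an inhibitory receptor (3.38-fold), Atp6v0d2, a subunit of the vacuolar proton pump (3.31-fold), Il1r2, the decoy receptor of interleukin 1 (3.28-fold), Esm1 (3.27-fold), the histone gene H2ac10 (3.13-fold) and Cxcl10, an interferon-induced chemokine (3.07-fold). Lilrb4a had the widest error of these, 1.76 ± 0.26 on the log2 scale. The 12 largest falls were led by Ptcd3, a mitochondrial ribosome protein gene, which fell by 1.35 ± 0.12, while its other probe set gave -0.32. Atp1b1, a sodium pump subunit, fell by 1.09 ± 0.11, and Gpr83, a receptor enriched in Treg, fell by 1.09 ± 0.15. Cpne4, Sox4, Actn1 and Satb1 fell by 0.98, 0.97, 0.90 and 0.88, and Ugcg, Vps37b, Zbtb10 and Zdhhc14 fell by 0.85, 0.85, 0.82 and 0.82. A dim second probe set of Sox4 gave -0.30. Of these 24 genes limma called 10 without anti-DR3 replicate 1, 0 without anti-DR3 replicate 2, 14 without control antibody replicate 1 and 22 without control antibody replicate 2, and the smallest difference among them had a size of 0.68, 0.73, 0.62 and 0.81 in these fits, against 0.82 with all 4 arrays.

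**Figure D1:**
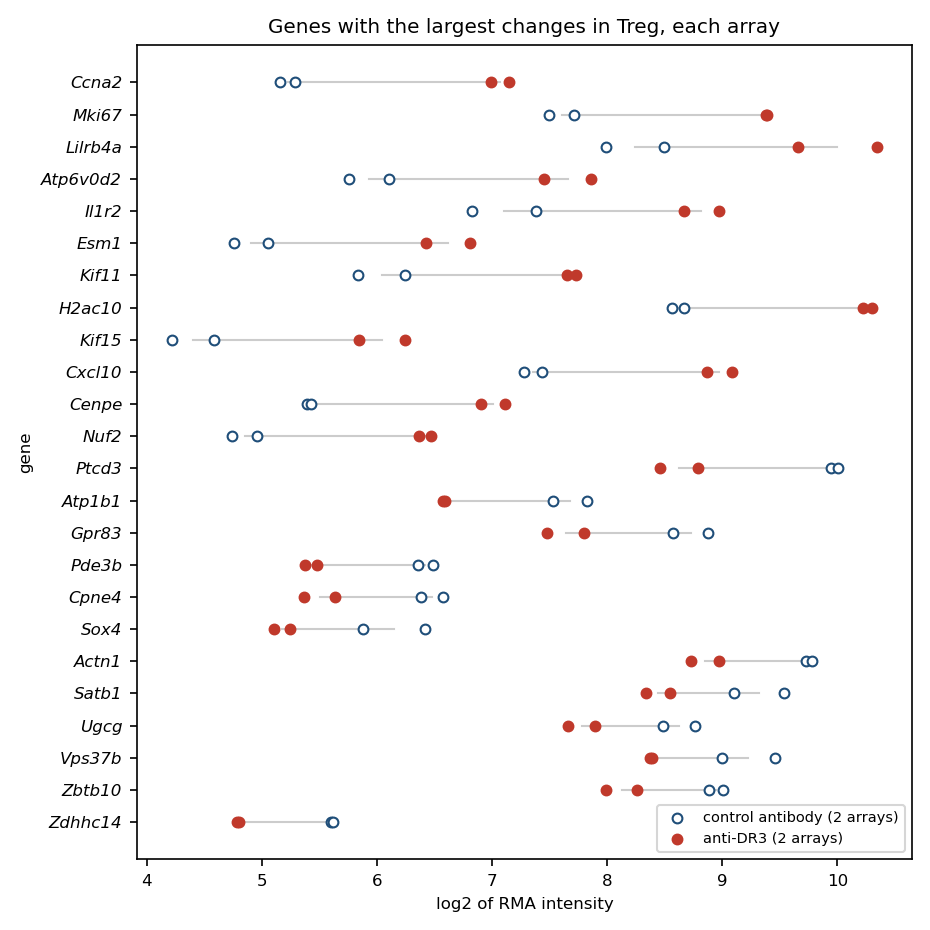
Log2 of RMA intensity on each of the 4 arrays (horizontal axis) for the 12 genes with the largest rise and the 12 with the largest fall (vertical axis), with filled points for anti-DR3, open points for control antibody and a grey line between the group means. Both anti-DR3 arrays lay above both control arrays for each rise, as for Ccna2 at 6.99 and 7.14 against 5.16 and 5.29, and below them for each fall.

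Of 36 measured mitosis genes 25 rose, 0 fell and 11 did not pass, with a median log2 difference of 0.90 (camera adjusted p = 2.87e-23; adjusted p = 0.215 with an estimated correlation). Ccnb2, a mitotic cyclin, rose 2.91-fold and Nusap1, a spindle protein, 2.60-fold. Adjusted over the list alone, 33 rose. Of 30 DNA replication genes 7 rose and 0 fell, with a median of 0.26 (camera adjusted p = 3.68e-05; adjusted p = 0.215 with an estimated correlation), and adjusted over the list alone 14 rose. They included the helicase subunit gene Mcm6 (1.56-fold), Tk1, the thymidine kinase (1.62-fold) and Cdc45 (1.51-fold).

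Of 32 effector Treg genes 25 rose, 0 fell and 7 did not pass, with a median of 0.74 (camera adjusted p = 1.24e-21; adjusted p = 0.215 with an estimated correlation), and 31 rose when adjusted over the list alone. S100a6 rose 2.88-fold, S100a4 2.35-fold, the galectin gene Lgals1 2.28-fold and Itgae, the integrin chain CD103, 2.41-fold. These belonged in part to the list of S100, annexin and cytoskeletal genes, which shared 3 members with it. In that list 12 of 23 rose and 0 fell, with a median of 0.52 (camera adjusted p = 1.10e-10; adjusted p = 0.215 with an estimated correlation), and 17 rose when adjusted over the list alone. Anxa2, which binds membranes and calcium, rose by 1.14 on the log2 scale.

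Of 22 resting Treg and naive T cell genes 10 fell, 0 rose and 12 did not pass, with a median of -0.48 (camera adjusted p = 1.36e-10; adjusted p = 0.409 with an estimated correlation). Adjusted over the list alone, 15 fell and 1 rose. Bach2, a repressor that holds T cells in a resting state, fell by 0.69 ± 0.089, and Bcl2, an inhibitor of cell death, fell by 0.78 ± 0.098, with -0.10 at a dimmer probe set. Markers of conventional CD4 T cells had 2 falls among 12 (Pde3b and Igfbp4) and 0 rises (camera adjusted p = 0.148), and adjusted over the list alone 3 fell and 2 rose.

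Among 22 Treg identity genes 2 rose, 3 fell and 17 did not pass, with a median of 0.24 (camera adjusted p = 0.0211; adjusted p = 0.409 with an estimated correlation), and adjusted over the list alone 9 rose and 3 fell. Ikzf2, the transcription factor Helios, rose by 0.58 and Entpd1, the ectoenzyme CD39, by 0.49. Gpr83 and Lrrc32, which presents latent TGF-beta, fell by 1.09 and 0.62. The last fall was Il2ra, a chain of the interleukin 2 receptor, at -0.49, which was named after its values were seen.

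Of 29 chemokine receptor and adhesion genes 11 rose, 1 fell and 17 did not pass, with a median of 0.31 (camera adjusted p = 1.57e-05; adjusted p = 0.215 with an estimated correlation), and adjusted over the list alone 15 rose and 2 fell. Ccr3 rose 2.89-fold, Ccr2 2.24-fold and the integrin gene Itga2 2.22-fold. Of 24 helper T lineage genes 9 rose and 2 fell, with a median of 0.27 (camera adjusted p = 0.000604; adjusted p = 0.259 with an estimated correlation), and adjusted over the list alone 13 rose and 3 fell. Il18rap and Il18r1, the chains of the interleukin 18 receptor, rose 2.36- and 1.75-fold. Of 10 markers of type 2 innate lymphoid cells 3 rose and 0 fell, with a median of 0.37 (camera adjusted p = 0.0117; adjusted p = 0.346 with an estimated correlation), and 5 rose when adjusted over the list alone. These were Klrg1, Rora and Il9r, and 3 of the 10 measured members also stood in the effector Treg list.

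Of 29 interferon-stimulated genes 7 rose and 0 fell, with a median of 0.38 (camera adjusted p = 6.73e-08; adjusted p = 0.409 with an estimated correlation), and 16 rose when adjusted over the list alone. Cmpk2 rose 1.58-fold, Zbp1, a sensor of nucleic acids, 1.53-fold and Isg20 1.45-fold. Oxidative phosphorylation had 2 rises among 31 genes, Cox5a and Atp5pb, with a median of 0.21 (camera adjusted p = 0.000354; adjusted p = 0.409 with an estimated correlation), and 7 when adjusted over the list alone. Glycolysis had 2 among 16, Tpi1 and Pgk1, both within the list alone as well, with a median of 0.19 (camera adjusted p = 0.0365; adjusted p = 0.409 with an estimated correlation). Of 32 immediate early genes of T cell receptor signalling 0 rose and 1 fell, Jun, by 0.58, also when adjusted over the list alone. Their median was -0.07 (camera adjusted p = 0.0144, and 0.346 with an estimated correlation) and ran from -0.14 to -0.03 across alternatives.

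Some lists that camera did not call held genes that passed. Of 23 TNF receptor superfamily genes 3 rose (camera adjusted p = 0.148, fry 0.0459), among them Tnfrsf1b, the receptor TNFR2, by 0.88 and Tnfrsf9, the costimulator 4-1BB, by 0.74, and 5 when adjusted over the list alone. Of 28 NF-kappaB targets 3 rose, Icam1, Nfkb2 and Nfkbie (camera adjusted p = 0.116), and 5 when adjusted over the list alone. Of 17 cytokine and cytotoxic genes 4 rose, namely Gzmb (2.12-fold), Ebi3 (1.76-fold), Il10 (1.57-fold) and Ccl5 (1.82-fold), with camera adjusted p = 0.197 and 0.034 on the log2 scale at a dim probe set of Ebi3, and adjusted over the list alone 7 rose and 2 fell. Apoptosis regulators had 4 rises and 1 fall among 24 (camera adjusted p = 0.185, fry 0.0459), with Casp1 and Casp4, caspases of inflammasomes, at 2.08- and 2.04-fold, and 6 rises and 2 falls when adjusted over the list alone. TNF superfamily ligands had 1 rise among 10, Tnfsf10 (camera adjusted p = 0.850, fry 0.0469), and 3 rises and 2 falls over the list alone, and their median of -0.03 and mean of 0.0049 differed in sign. Cholesterol and fatty acid synthesis (22 genes, camera adjusted p = 0.217), the T cell receptor complex (21 genes, 0.597) and ribosomal proteins (26 genes, 0.191) had 0 calls in limma, over all genes and over the list alone, with 5, 6 and 2 members under an unadjusted p of 0.05.

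Apart from the markers of type 2 innate lymphoid cells, camera called no marker list, while fry also called the B cell (adjusted p = 0.0322), plasma cell (0.0421), dendritic cell (0.0322) and conventional CD4 T cell (0.0469) lists, and some B cell markers rose with the groups above. Of 9 B cell markers Ighm (1.55-fold), H2-Aa (1.62-fold) and H2-Ab1 (1.47-fold) rose and 0 fell (camera adjusted p = 0.293), also when adjusted over the list alone. A second bright probe set of Ighm gave 1.18 on the log2 scale against 0.63, and 5 dim ones lay between -0.36 and 0.098. Plasma cell markers had 1 rise among 8, Irf4 (camera adjusted p = 0.148), and 2 over the list alone. CD8 T cell markers had 2 among 7, Ccl5 and Cd8b1, in both adjustments (camera adjusted p = 0.514), and monocyte and macrophage markers 1 among 16, Csf1r, and 3 over the list alone (camera adjusted p = 0.217). Dendritic cell markers (5 genes, camera adjusted p = 0.480), natural killer and type 1 innate lymphoid cell markers (5 genes, 0.597) and stromal, endothelial and epithelial markers (10 genes, 0.480) had 0 calls in limma over all genes, with 2, 1 and 1 members under an unadjusted p of 0.05. Adjusted over the list alone these had 1 rise, 1 fall and 1 fall. The natural killer list had a median of 0.03 and a mean of -0.02. Of 7 symbols counted as immunoglobulin segments 2 rose, Ighm and Ighg3, the latter named after its values were seen, and of 6 counted as T cell receptor segments 0 changed in limma, with 2 under an unadjusted p of 0.05.

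**Figure D2:**
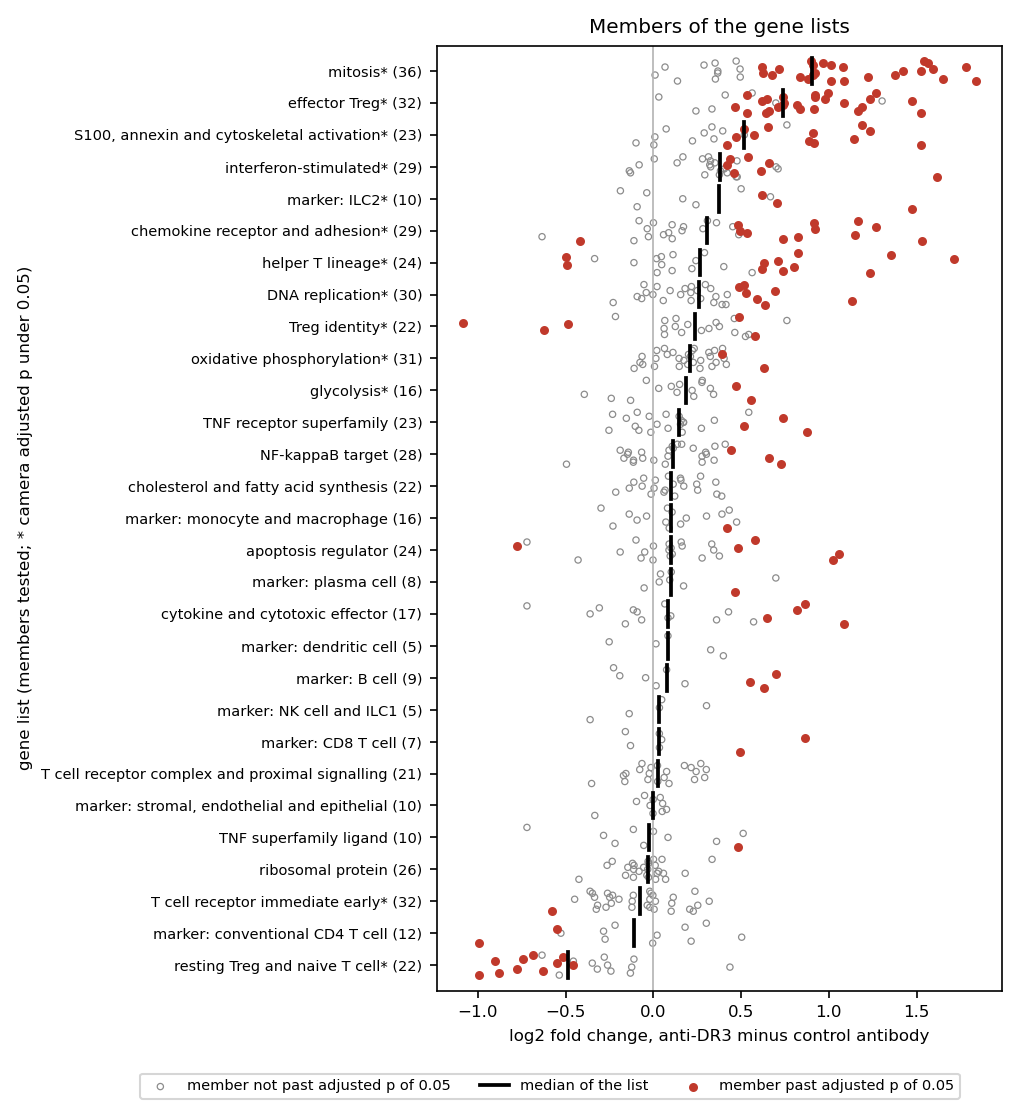
Log2 difference, anti-DR3 minus control antibody, of each measured member (points, horizontal axis) of the 29 gene lists tested (vertical axis, number of members in parentheses), with black bars at list medians, filled points for members past an adjusted p of 0.05 in limma and a star where camera passed at its preset correlation. List medians ran from 0.90 for mitosis to -0.48 for resting Treg and naive T cell genes.

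Camera called 13 of the 29 lists, 11 higher and 2 lower, and with an estimated correlation 0 (smallest adjusted p = 0.215, 5 under an unadjusted p of 0.05), while fry, which does not compare a list with other genes, called 17, of which 10 were shared with camera. The correlation estimated by camera lay below the preset 0.01 for DNA replication (-0.028), chemokine receptor (-0.010) and helper T lineage genes (-0.0037). It did so too for immediate early genes (-0.014) and innate lymphoid markers (-0.080). For these lists a higher correlation was therefore not what ended the call. For the other called lists it lay between 0.016 and 0.47. Since the calls above ended without a higher correlation, these values do not show that correlation ended the others. Fry did not call resting Treg and naive T cell (adjusted p = 0.0599), interferon-stimulated (0.0624) or glycolysis genes (0.1001). The calls of Treg identity and immediate early genes were lost in camera without control antibody replicate 2 (adjusted p = 0.0594 and 0.0667), the former also under the stricter filter on dim genes (0.119) and the latter with no filter (0.0640), over ranges of 0.0013 to 0.119 and 0.00098 to 0.0667 across alternatives other than the estimated correlation, and glycolysis kept its call in 7 of 14. NF-kappaB targets gained a call with no filter on dim genes (camera adjusted p = 0.0127). Cytokine and cytotoxic genes gained one under the stricter filter (camera adjusted p = 0.0209). Without control antibody replicate 1 the cholesterol and fatty acid list had a median of 0.18, against 0.10 with all 4 arrays. Summed over lists, 147 members passed over all genes and 237 when adjusted over the list alone.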

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

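Over the named genes and their alternatives, 1139 values kept direction and side of the threshold, 324 lost the call, 43 gained one and 7 turned direction, and for lists these were 378, 26, 10 and 14. With each array left out in turn, the lone array being assumed to vary like the other group, limma called 0 to 312 genes, 0 to 245 higher and 0 to 67 lower, and 0 to 2 immunoglobulin segments; the fit with 0 had 1967 genes under an unadjusted p of 0.05. No filter on dim genes gave 14 genes, 14 higher and 0 lower, and 0 immunoglobulin segments, with 3573 under an unadjusted p of 0.05 and a prior of 3.32 degrees of freedom against 3.94. The stricter filter gave 1281 (951 higher, 330 lower) and a trended robust prior 1444 (1082 and 362), each with 1 T cell receptor segment, Trav7-4, named after its values were seen. Centring on the array median gave 348 higher. Every probe set tested on its own gave 0, 0 higher and 0 lower (4121 unadjusted, smallest adjusted p = 0.0764), and the ordinary linear model 0 of each (2087 unadjusted, smallest adjusted p = 0.108); the causes of these differences were not tested. An adjusted p under 0.10 gave 1689 (1171 and 518), a 2-fold minimum beside the threshold 72 (69 and 3), and 2-fold without overlap and with no p 76 (73 and 3). The mean of all probe sets gave 1 immunoglobulin segment. Protein-coding genes alone, chosen after seeing the data, gave 111 lower. Camera with an estimated correlation called 0 lists. The labels do not say what the replicate numbers share. Differences between replicates correlated at 0.051 across genes between the groups. These are only 2 pairs, so this cannot show whether replicates were paired. The replicate block gave 563 genes, 430 higher and 133 lower, of which 497 were shared with the main fit. It also ended the call of glycolysis (camera adjusted p = 0.0643, range over its alternatives 0.00194 to 0.409). Of single values that turned direction, none was called: centring gave Eomes -0.013, the T cell receptor complex -0.036, and CD8 T cell and natural killer markers -0.026 each. The mean of probe sets gave Rpl3 -0.091, from 0.33 at the probe set used, -0.48 at another bright one and -0.13 at a dim one, and quantile normalization gave natural killer markers -0.016 and stromal markers 0.038. Both other filters put TNF ligands at 0.00067. With each array left out, ranges were -0.38 to 0.062 for Gzmk, -0.20 to 0.013 for Gp9, -0.33 to 0.051 for Tyrobp, -0.20 to 0.29 for Eomes and -0.11 to 0.014 for Pecam1. List medians ranged from -0.033 to 0.025 for TNF ligands, -0.010 to 0.041 for the T cell receptor complex, -0.11 to 0.20 for CD8 T cell markers, -0.20 to 0.17 for natural killer markers and -0.048 to 0.013 for stromal markers. Only 4 arrays were present, which limits precision, and dim genes lie near background.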

Other observations

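Small nucleolar RNAs (snoRNAs), which guide the chemical modification of ribosomal RNA, were lower after anti-DR3, a class looked at only after the data had been seen. Of 70 tested, 37 fell and 0 rose in limma, 69 had a negative difference and the median was -0.50. They made up 20.8% of the genes that fell and 0.578% of those tested (Fisher's exact test, two-sided, odds ratio 94.2, p = 1.98e-50, with genes that are not independent). Camera gave p = 1.78e-30 at the preset correlation and p = 0.0762 with an estimated correlation. Without anti-DR3 replicate 1 or replicate 2 limma called 0 of them (49 and 46 under an unadjusted p of 0.05), without control antibody replicate 1 it called 2 and without control antibody replicate 2 it called 17, while their median stayed between -0.59 and -0.45. With no filter on dim genes limma called 0 of the 70 snoRNAs, at the same median of -0.50, and with the stricter filter 44 of 60. Of 144 microRNA genes 5 fell and 0 rose.

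The patterns below were found in these data and are hypotheses. The tests on other short RNAs, on markers of other cell types, on a shift of all genes and on Foxp3 were chosen after the result was seen, and those on short RNAs without microRNA, innate lymphoid cells and B cells after the pooled tests; those on host genes, snoRNA length, centring and splits were set out before their result but after the pattern itself.

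Lower snoRNA signal may reflect biology or RNA handling. The 43 measured host genes had a median of 0.0020 (bootstrap 95% interval -0.09 to 0.08), so host RNA did not fall with the class as a whole. The arrays measured RNA levels and not transcription, so a change in host transcription stays open. Nop58, Nop56 and Gnl3 fell by 0.45, 0.47 and 0.43 and Snhg1 and Snhg12 were at -0.37 and -0.34, all named after their values were seen. Of the 51 snoRNAs whose measured host did not pass, 22 fell. Of other short RNAs 37 had a median of -0.16 (-0.24 to -0.05, close to the bound of -0.25), but 24 of them were microRNA genes at -0.14, so this argues only against an equal loss that takes in microRNA. Without these the median of 13 was -0.25 (-0.51 to -0.13) and 6 fell. Guide RNAs were at -0.58 and gave 3 of these 6 falls, from 4 measured. RNase P RNA was at -0.32 and small nuclear RNAs at -0.25, while Y RNA (-0.19) and telomerase RNA (0.013) were not called. A loss of other short RNAs cannot be told apart from a change in the cells while the interval of the 13 spans the bound. Nor can size-dependent recovery, with length and difference correlated across the 70 snoRNAs at rho = 0.071 (-0.169 to 0.300).

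Higher effector and mitotic genes could come from other cells in the sort or from a shift between arrays. After centring on the array median the lower of the list medians was 0.68. The array medians of tested genes lay close together (6.81 and 6.81 after anti-DR3, 6.77 and 6.73 after control antibody). Centring could therefore move the lists only slightly, and its outcome was all but fixed. It shows only that the lists rose by more than the array medians differed. The share of higher genes among calls was 75.3% as deposited, 73.7% when quantile normalized again and 58.9% after centring. Centring lowers every difference. The median difference of the tested genes was 0.010 before centring, less than the gap between the array medians, so centring removed more than that median. The 58.9% therefore does not show that scaling made the excess of rises, and the part of scaling in that share stays open. Type 2 innate lymphoid cells were set apart. The 51 markers of other cell types held by no T cell list had a median of 0.041 (-0.00096 to 0.083). Of these 5 were higher and 0 lower, beside 544 higher and 178 lower among all 12114 genes tested. They thus did not rise as a pool, which leaves a small share of other cells, or a single type, open. Some lay near background, as Col1a1 and Cd22 at 5.50 and 5.66 after control antibody against array medians of 5.38 and 5.39. Others were bright, as Pecam1 at 9.18. Dimmer markers were not tested, with 9 of 19 B cell and 5 of 15 natural killer markers on the array passing the filter. The 6 innate lymphoid markers held by no T cell list had a median of 0.33 (-0.11 to 0.69). Il9r was at 0.70, Il17rb at 0.67, Ptgir at 0.50 and Arg1 at 0.17, but Hpgds at -0.19 and Alox5 at -0.04. The 9 B cell markers had a median of 0.076 (-0.19 to 0.63), with Ighm, H2-Aa and H2-Ab1 higher. Cd79b was at 0.18, H2-Eb1 at 0.08, Ly6d at 0.02, Cd22 at -0.04, Bank1 at -0.19 and Fcmr at -0.23. Markers outside the naming rule were chosen after their values were seen. A share of either type stays open, although a gate on CD4 and the Foxp3 reporter would remove both, as does activation or expansion of Treg, which was not tested further.

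Treg identity genes moved apart, with Ikzf2 and Entpd1 higher and Gpr83, Lrrc32 and Il2ra lower. Fewer Foxp3 cells in the sort might lower such genes. Foxp3 differed by 0.064 (95% interval -0.134 to 0.262), above the -0.49 of Il2ra. The gate on a Foxp3 reporter itself favours a level Foxp3, so this shows only that Foxp3 RNA did not fall with Il2ra. A change of state within Treg stays open and was not tested.

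Of the 3 ways to split the 4 arrays into 2 and 2, 1 gave as many genes as the 722 of the real comparison, namely that comparison itself, and the highest of the others gave 0. Those others put 1 anti-DR3 and 1 control array on each side, so a treatment difference would widen their spread and lower their count. The splits are too few for a share under 0.05.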
